A study of Mus musculus with 12 samples.

How the data were processed

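RNA from primary mouse cortical cultures was sequenced in 12 libraries, 4 in each of 3 groups. The floxed GFP group came from mice with loxP sites in both copies of Satb2, without Cre recombinase. The knockout GFP group carried the same floxed gene and Cre under the Nestin promoter, which is active in neural progenitors. Both groups received an adeno-associated virus (AAV) that makes green fluorescent protein (GFP) from the human synapsin promoter, a promoter active in neurons. The knockout SATB2 group was the same knockout with a virus that makes V5-tagged SATB2 from that promoter. Groups and replicate numbers were taken from the titles. Per the labels' protocols, cells from newborn pups were transduced on day 4 in vitro at a multiplicity of 33000, given 5 µM cytosine arabinoside on day 3 to stop dividing cells, silenced with 20 µM NBQX (an AMPA receptor blocker) for 16 h from day 13, and exposed to 50 µM bicuculline (a GABA-A receptor blocker that raises network activity) for 1 h before collection on day 14. The labels do not say whether the 4 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

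The deposited table held whole numbers for 23200 genes in 12 columns, named by gene symbol, and each column matched the title of 1 library. The submitters' processing notes name the mm10 build, STAR 2.7.6a, SAMtools 1.11, deepTools 3.3.3, featureCounts, Subread 2.0.1 and DESeq2, with no role or order given. Whether reads were counted by strand is not given in the sources used here, so overlapping genes on opposite strands may share reads. The values are not raw counts. On the log2(value + 1) scale the 12 columns spanned only 7 dimensions over the 11410 genes with a value of at least 200 in every library. The other 5 singular values, between 0.000545 and 0.000582, matched the 0.000565 that rounding to whole numbers gives, against 0.109 for the seventh. Column totals lay between 46109798 and 48693376. The table therefore held adjusted score values, deposited by the authors after 5 directions of variation between the libraries had been taken out and the result rounded. The step that did this is not described in the sources used here. The sequencing depth behind each value is unknown, so no counting interval or detection floor is given.

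The taken-out directions were not balanced over the groups. They held 11.6% of the squared length of the knockout GFP minus floxed GFP contrast, 46.2% of knockout SATB2 minus knockout GFP and 76.8% of knockout SATB2 minus floxed GFP. A difference of plain group means in the adjusted values therefore mixes the 3 groups. For this reason limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with the 3 group means and 5 terms for the taken-out directions (lmFit, contrasts.fit, eBayes with a trend and robust settings), which left 4 residual degrees of freedom. If the values are the log values less their projection on those directions, this fit gives the group effects of the unadjusted log values with the 5 factors as covariates. That reading is an assumption, which the values used here do not test. The terms inflated the standard deviation of the 3 contrasts by 1.16, 1.87 and 2.32 times. The factors may hold biology as well as unwanted variation, and what was taken out cannot be recovered.

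The design fixed beforehand assumed raw counts and a quasi-likelihood count test with a TMM scaling. That test does not suit adjusted values, so limma took its place, and count-based alternatives were not run. Genes with a value of at least 10 in at least 4 libraries were tested (19054 of 23200), with Benjamini-Hochberg adjustment at 0.05 within each contrast. Fold changes are on the log2(value + 1) scale, are given with the standard error (SE) of limma, and understate changes of low genes. CPM (the adjusted values scaled to equal library totals) served only for filters and for the overlap rule below. Positions come from the GENCODE annotation of mm10, in which the genes called in the report with a position were protein-coding.

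Genes were named by a rule written before the data were examined. Satb2 came first. For each contrast the rule took the 10 genes with the strongest rise and the 10 with the strongest fall among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the 4 and 4 libraries in CPM, and passed over gene models without a proper name. Reversed genes, which are those past the threshold in opposite directions in the knockout contrast and in the SATB2 against knockout contrast, were ranked by the larger of both adjusted p-values, and up to 10 of each direction were taken. From each gene list, up to 4 members past the threshold were taken by adjusted p, and otherwise the 2 members with the highest CPM. The 21 lists (447 entries) were also fixed beforehand. Of the genes the rule took, 1 is not reported here. Of the entries, 427 matched by symbol, 2 by a synonym and 18 were not matched to a row of the table. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the 21 lists. With an estimated correlation camera uses no more than the 4 residual degrees of freedom, so that test is weak for every list. A list that does not pass it is not shown to be unchanged.

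The recovery slope is minus the covariance of the knockout and SATB2 fold changes over the variance of the knockout fold change, across genes without Satb2, each less its error part. Its error came from the residual directions of the libraries. Because both contrasts use the knockout GFP libraries, unchanged groups were simulated with the same directions taken out (100 simulations), and the knockout GFP libraries were split 2 and 2 in 6 ways. Noise in the simulations was drawn for each gene alone. The limma step was tested on simulated data with 200 changed genes among 19054. The same 5 directions were projected out of these data, so the test takes that reading of the values as given. It cannot support the reading, and the gain from the 5 terms is built in. With the 5 terms it recovered 90.3% of genes changed by 2 on the log2 scale in the knockout against floxed contrast, 78.5% in SATB2 against knockout and 71.2% in SATB2 against floxed. At a change of 1 the shares were 71.3%, 54.6% and 46.3%, and at 0.5 they were 51.0%, 14.0% and 5.07%. False calls were 6.47%, 10.9% and 10.2% of all calls. Without the terms, the median estimate for a change of 2 was 0.790, 0.324 and 0.115 of the true value in the same order, and 36.8% of calls in the knockout contrast were false.

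Within groups, 2 libraries of knockout SATB2 (replicates 3 and 4) had a median chi-square per gene of 1.15 and 2 of floxed GFP (replicates 1 and 4) had 1.48, against 3.29 to 8.36 for the pairs in knockout GFP. These libraries kept between 0.183 and 0.425 of their own direction after the adjustment, as a share of its squared length. Sampling noise cannot be set for adjusted values, and Satb2 differed within the pairs (13099 and 30935 in knockout SATB2, 28298 and 33857 in floxed GFP), so they were kept as separate samples. Alternatives were median-of-ratios rescaling, no low-value filter, a filter of at least 1 CPM in at least 4 libraries (15163 genes), the replicate number as a block, only the 2 groups of a contrast in the fit, and leaving out each library in turn. Chosen after seeing the data were a fit of group means alone (9 residual degrees of freedom), pseudocounts of 0.5 and 4, and the filter of 10 in 4 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.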

Results

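Satb2 encodes a nuclear DNA-binding protein of upper-layer cortical projection neurons, and the series asks how it organises the genome in cortical neurons. Total RNA was measured in cultures of 3 kinds, each with 4 libraries: floxed cultures with a GFP virus, Satb2 knockout cultures with the GFP virus, and knockout cultures with a virus that makes SATB2. All cultures were silenced and then stimulated with bicuculline for 1 h before collection on day 14. The deposited values are adjusted and rounded, with column totals from 46109798 (floxed GFP replicate 1) to 48693376 (knockout GFP replicate 4), so these totals are not sequencing depths. Between 66 and 638 of the 23200 genes were listed at 0 in a library. Fold changes below come from limma with 5 terms for the taken-out directions.

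Satb2 (mm10 chromosome 1, 56793981 to 56978650, minus strand) was lower in knockout GFP than in floxed GFP cultures and far higher with the SATB2 virus. Deposited values averaged 28254 ± 13226 (SD, n = 4) in floxed GFP, 5692 ± 4909 (SD, n = 4) in knockout GFP and 35303 ± 29164 (SD, n = 4) in knockout SATB2. The model gave a log2 fold change of -1.64 ± 0.22 (SE) in the knockout (adjusted p = 0.00209). With the virus, Satb2 was in this model 78.0-fold above the knockout level, a log2 difference of 6.29 ± 0.35 (SE; adjusted p = 0.00428), and above the floxed level by 4.64 ± 0.44 (adjusted p = 0.00543). The model levels behind these values were 7174 in floxed GFP, 2295 in knockout GFP and 179141 in knockout SATB2. Deposited values ran from 9980 to 40881 in floxed GFP and from 13099 to 77628 in knockout SATB2. The model level of floxed GFP lay below, and that of knockout SATB2 above, all deposited values of its group. All 3 differences thus rest on model levels outside the deposited values. Floxed GFP replicate 3, at 9980, lay below knockout GFP replicate 3, at 12353. The labels do not name the deleted part of the gene or the species of the vector's reading frame, so signal in the knockout can come from transcript outside the deletion, and virus and cell transcripts are not separated. In plain group means, which mix the groups, the differences were -2.57 ± 0.73, 2.73 ± 0.73 and 0.16 ± 0.73, the last with an adjusted p of 0.988. Without floxed GFP replicate 3 the calls against floxed cultures were lost (-1.57 ± 0.36, adjusted p = 0.0600 for the knockout, and 4.79 ± 0.75, adjusted p = 0.177 for SATB2), as was the call of SATB2 against knockout without floxed GFP replicate 1 (6.32 ± 0.45, adjusted p = 0.0552). The differences in these fits were of similar size to those above, with higher SE. Without floxed GFP replicate 4 the calls held, but the SATB2 differences on the log2 scale were 7.33 against knockout and 5.70 against floxed cultures.

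**Figure D1:**
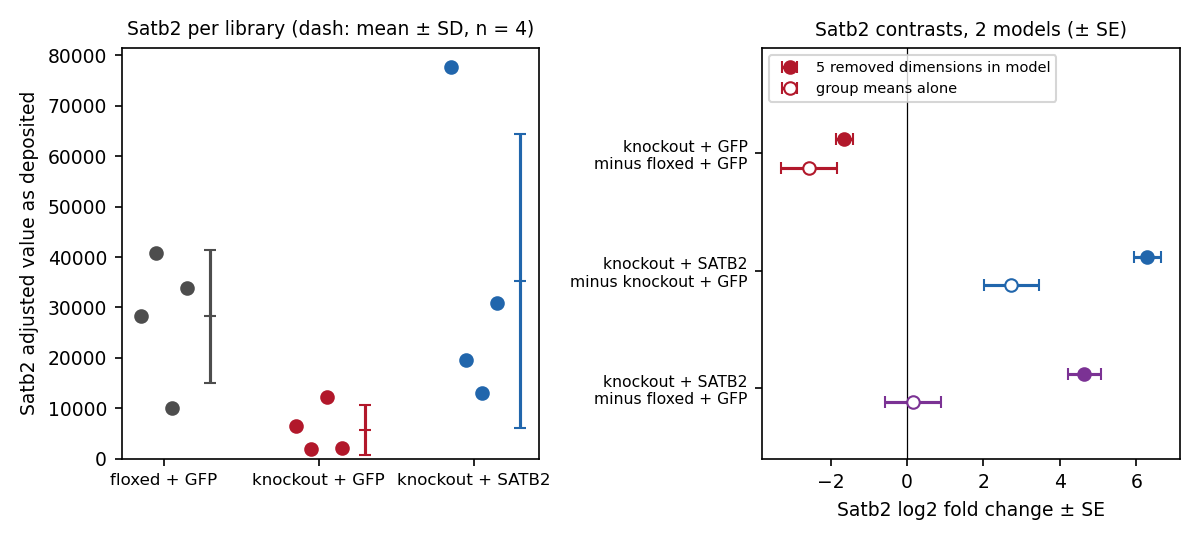
Left, Satb2 adjusted value as deposited for each of the 12 libraries (points) with the mean and SD of each group (bars, n = 4). Right, log2 fold changes of Satb2 with SE in 3 comparisons, from the model with the 5 taken-out directions (filled) and from group means alone (open); the SATB2 against floxed difference is 4.64 in the first and 0.16 in the second.

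The first comparison asks which transcripts differ when neurons lack Satb2. Of 25 upper-layer and callosal neuron genes, 15 fell and 4 rose in knockout cultures, and of 19 subcerebral and 14 layer 6 neuron genes, 8 and 4 rose. As lists these passed camera with its preset correlation, but not the weaker test with an estimated one (upper-layer adjusted p = 0.610, subcerebral 0.347, layer 6 0.610). Bcl11b (chromosome 12, 107910403 to 108003602, minus strand), which encodes the transcription factor CTIP2 of subcerebral projection neurons, rose by 2.31 ± 0.08 on the log2 scale (SE, n = 4 per group; adjusted p = 4.21e-08). Dkk3, a secreted glycoprotein of the Dickkopf family found on the upper-layer list, changed by -3.57 ± 0.26, and Nectin3, a cell adhesion gene, by -1.24 ± 0.10. Of 19054 genes tested, 2785 changed, 1336 higher and 1449 lower in the knockout, and 936 of them differed by more than 2-fold (416 higher, 520 lower). After median-of-ratios rescaling 1535 were higher and 1333 lower, so which direction was in excess depended on the scaling. At an unadjusted p of 0.05 there were 5159, where chance gives 953.

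Among the genes the rule names, the strongest rise was that of Scel, which encodes sciellin (chromosome 14, 103513342 to 103612797, plus strand), with deposited means of 35.8 ± 14.5 and 286 ± 88.9 (SD, n = 4 each). The model, whose folds are not ratios of these means, gave Scel a 9.72-fold difference (3.28 ± 0.27; adjusted p = 7.26e-06). Chrna5, a nicotinic acetylcholine receptor subunit, rose 9.19-fold, Cr2, a complement receptor, 8.99-fold, and Epyc, a small proteoglycan, 7.79-fold. Bmpr1b, a BMP receptor, was 7.63-fold higher, Rxrg, a retinoid X receptor, 6.98-fold, Anln, which encodes the actin-binding protein anillin, 6.95-fold, and Ntng1, which encodes the axonal adhesion protein netrin-G1, 6.95-fold. Ndst4, a heparan sulfate modifying enzyme, and Crym, a thyroid hormone binding protein, were 6.81-fold and 6.67-fold higher. Standard errors of these 10 genes lay between 0.13 and 0.27 on the log2 scale. The strongest fall was in Aldh1a3, a retinoic acid synthesising enzyme (chromosome 7, 66390890 to 66427517, minus strand), at 368 ± 401 in floxed GFP and 12.3 ± 5.38 in knockout GFP (SD, n = 4 each; log2 fold change -5.23 ± 0.54, adjusted p = 0.000115). Trpc6, a cation channel, had a log2 fold change of -3.77 ± 0.25, Grp, gastrin-releasing peptide, of -3.35 ± 0.24 and Bmp2, a secreted growth factor, of -3.32 ± 0.24. Tshz2, a zinc finger factor, stood at -3.22 ± 0.21, Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, at -3.21 ± 0.14, Klhl4 at -3.02 ± 0.19 and Kcnj16, an inward rectifier potassium channel, at -3.01 ± 0.42. Adjusted p-values of these genes were at most 0.000928.

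**Figure D2:**
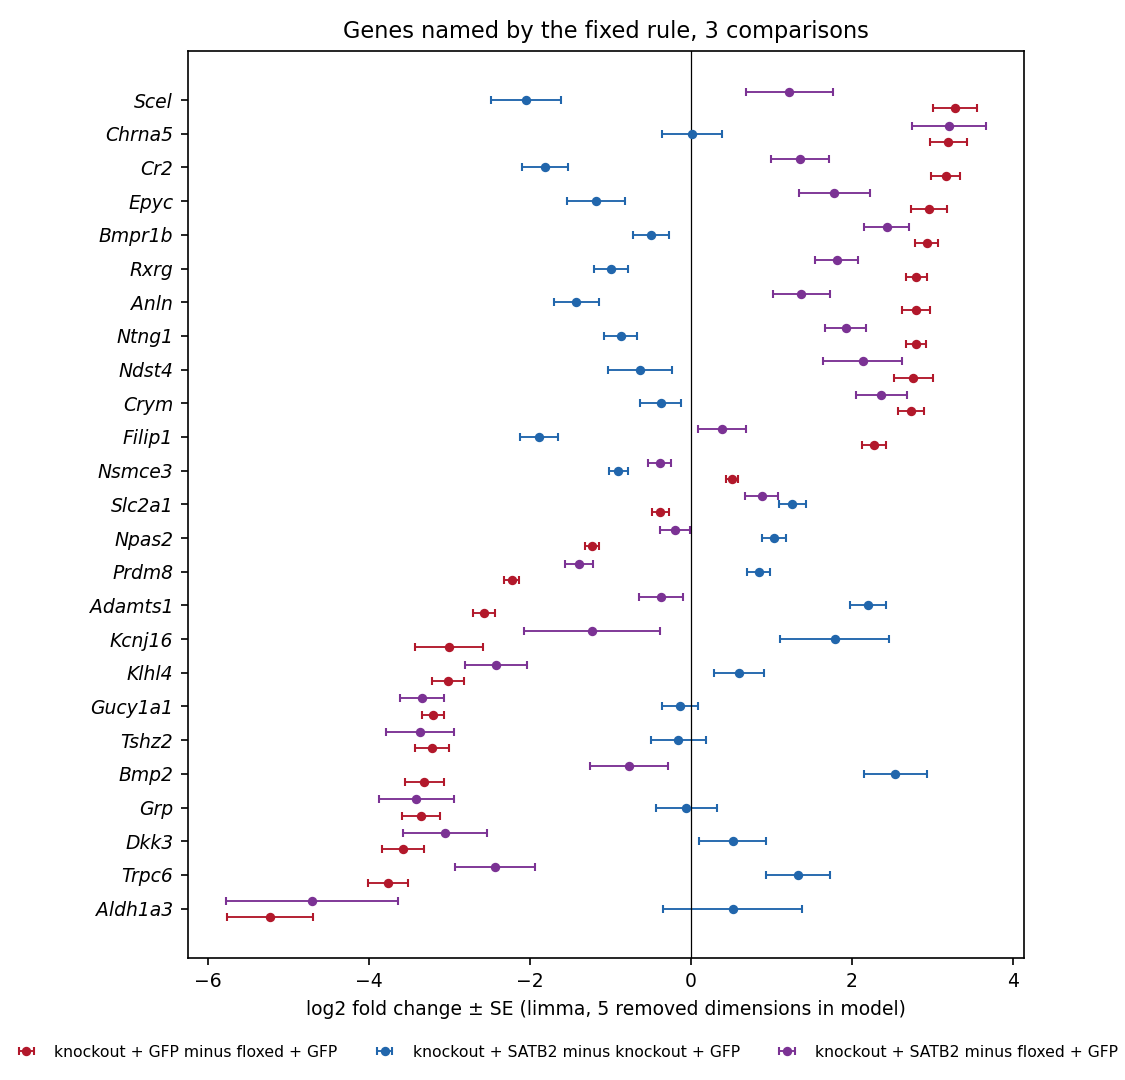
Log2 fold changes (points) with SE (bars) of the genes named by the fixed rule, in the 3 comparisons, from limma with 4 libraries per group. Chrna5 is at 3.20 in the knockout against floxed cultures and at 3.21 in knockout SATB2 against floxed cultures, while Bmp2 is at -3.32 and -0.77. Deposited means of Chrna5 were 113 in floxed GFP, 545 in knockout GFP and 206.5 in knockout SATB2, so its place depends on the terms in the model.

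Of the 21 gene lists, 8 passed in this comparison. Among 25 upper-layer and callosal genes, 15 fell, 4 rose and 6 did not pass (6 higher and 16 lower when adjusted over the list alone). The list median was -0.85 (camera adjusted p = 3.54e-05, and adjusted p = 0.610 with an estimated correlation). Besides Nectin3, log2 changes were -1.99 ± 0.17 for Nnmt, -1.37 ± 0.12 for Chn2, a Rac regulator, and -1.21 ± 0.10 for Rasgrf2, a Ras exchange factor. The 4 that rose were Plxnd1 (1.14), a semaphorin receptor, Mdga1 (1.08), an adhesion protein, and the transcription factors Pou3f3 (0.42) and Cux1 (0.28), named after their values were seen. Of 19 subcerebral genes, 8 rose, 3 fell and 8 did not pass (9 and 3 over the list alone), with a median of 0.44 (adjusted p = 0.00123, and adjusted p = 0.347 with an estimated correlation). Besides Bcl11b and Crym, Cntn6, a neural adhesion gene, rose by 2.51 ± 0.12 and the repressor gene Bcl6 by 1.43 ± 0.11. The 3 that fell were Ldb2 (-2.07), Fezf2 (-0.79), a transcription factor that specifies these neurons, and Cdh22 (-0.33), also named after their values were seen. Of 14 layer 6 and subplate genes, 4 rose (Ppp1r1b 1.76 ± 0.13, Sla 1.68 ± 0.10, Sox5 1.42 ± 0.09, Tle4 0.64 ± 0.11), 1 fell (Ntsr1, -0.48) and 9 did not pass (4 and 2 over the list alone). That list had a median of 0.20 (adjusted p = 0.0147, and adjusted p = 0.610 with an estimated correlation).

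Of 29 rapid activity genes, 6 fell, 0 rose and 23 did not pass (3 higher and 10 lower over the list alone), with a median of -0.28 (adjusted p = 0.00604, and adjusted p = 0.778 with an estimated correlation). Log2 changes were -1.04 ± 0.10 for Dusp6, a phosphatase of the ERK pathway, -1.20 ± 0.15 for Ier2, -0.96 ± 0.10 for Ier5 and -0.55 ± 0.10 for the nuclear receptor gene Nr4a1. Fos and Arc, named after their values were seen, stood at -0.34 ± 0.22 and -0.31 ± 0.35 and did not pass. Of 20 slower activity genes, 11 fell, 2 rose and 7 did not pass (11 lower and 2 higher over the list alone), with a median of -0.41 (adjusted p = 7.79e-05, and adjusted p = 0.610 with an estimated correlation). Ptgs2, an inducible cyclooxygenase, changed by -2.06 ± 0.16, Sorcs3 by -1.27 ± 0.13 and the growth factor gene Bdnf by -0.76 ± 0.09, whereas Nrn1, which encodes neuritin, rose by 1.68 ± 0.10. Of 19 cell stress and p53 target genes, 7 fell and 12 did not pass (8 lower over the list alone), with a median of -0.27 (adjusted p = 0.00249, and adjusted p = 0.610 with an estimated correlation). Examples were Cdkn1a at -1.35 ± 0.15 and Pmaip1 at -0.86 ± 0.15.

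Of 24 GABAergic interneuron genes, 7 fell, 2 rose and 15 did not pass (10 lower and 3 higher over the list alone), with a median of -0.28 (adjusted p = 0.0260, and adjusted p = 0.778 with an estimated correlation). The neuropeptide genes Sst and Npy changed by -0.99 ± 0.13 and -0.92 ± 0.10, and the transcription factor gene Arx by -0.49 ± 0.10, while Vip rose by 0.82 ± 0.11. Of 13 mitochondrially encoded genes, 2 rose (mt-Nd2 0.37 ± 0.09, mt-Nd1 0.23 ± 0.07) and 11 did not pass (4 over the list alone), with a median of 0.20 (adjusted p = 0.00604, and adjusted p = 0.610 with an estimated correlation). Markers of astrocytes did not pass as a list (adjusted p = 0.0542), with Slc1a3 at 0.74 ± 0.11, Clu at 0.73 ± 0.11, Gfap at 0.78 ± 0.14 and Aldoc at 0.92 ± 0.19 higher and 14 of 18 members not past the threshold (4 higher when adjusted over the list alone). None of the 8 list calls held with an estimated correlation, at which camera passed 0 of the 21 lists in any comparison (1, 0 and 1 in the 3 comparisons at an unadjusted p of 0.05). The estimated correlation of the subcerebral list was 0.00295, under the preset 0.01, so a higher correlation was not why its call was lost. That test rests on 4 residual degrees of freedom. The interneuron call was lost without knockout GFP replicate 3 (adjusted p = 0.174) and floxed GFP replicates 1 and 3 (0.337 and 0.798). The rapid activity call was lost without knockout GFP replicate 1 (0.0504) and floxed GFP replicate 2 (0.0553). The layer 6 call was lost without knockout GFP replicate 1 (0.0662) and in group means alone (0.156). In group means alone the stress list passed with a median of -0.17. The count of 2785 fell to 750 without knockout GFP replicate 3 and to 784 without floxed GFP replicate 3, and was 5235 (2417 higher, 2818 lower) in group means alone, 2686 of them shared.

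The second comparison asks what SATB2 from the virus changes in knockout neurons. Few genes passed: 7 of 19054, 5 higher and 2 lower (8 and 2 after median-of-ratios rescaling), of which Satb2 was the first. Adamts1, a secreted metalloprotease gene (chromosome 16, 85793827 to 85803113, minus strand), was higher with SATB2 by 2.20 ± 0.22 on the log2 scale (SE, n = 4 per group; adjusted p = 0.00932 in limma), against -2.57 ± 0.14 in the knockout. Npas2, a clock transcription factor gene (chromosome 1, 39193731 to 39363236, plus strand), was 2.04-fold higher (1.03 ± 0.15; adjusted p = 0.0348). Filip1, which encodes a filamin-binding protein (chromosome 9, 79815051 to 80012851, minus strand), was lower, at -1.89 ± 0.24, as was Nsmce3, a subunit of the SMC5/6 complex (chromosome 7, 64867052 to 64872997, minus strand), at -0.90 ± 0.12 (adjusted p = 0.0207 for both). Slc2a1, the glucose transporter GLUT1, was 2.39-fold higher, and Adamts8, chosen after its values were seen, was 2.34-fold higher. Their libraries overlapped in the deposited values.

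Of these genes, 6 were reversed, that is changed in opposite directions by the knockout and by SATB2: Satb2, Adamts1, Npas2 and Slc2a1 were lower in the knockout and higher with SATB2, and Filip1 and Nsmce3 the other way round. Satb2 was deleted in the knockout and supplied by the virus, so its reversal followed from the design. Only the other genes bear on reversal. The count of 6 became 0 without floxed GFP replicate 3, 1 without knockout GFP replicate 2, and 2 without SATB2 replicate 1 or 3 or floxed GFP replicate 4. It was 13 without knockout GFP replicate 4, 16 and 15 without floxed GFP replicates 1 and 2, 22 without SATB2 replicate 4, and 15 without a low-value filter. Limma called 0 genes in the same direction in both. Independent lists would share 0.140 genes in the first-higher direction and 0.380 in the first-lower direction. These values count Satb2 and do not allow for the knockout GFP libraries that both contrasts use. Among the 20 genes that the rule took for the knockout, 16 had the opposite sign with SATB2 and 0 passed. Scel was at -2.05 ± 0.44, Cr2 at -1.81 ± 0.29, Bmp2 at 2.54 ± 0.39 and Kcnj16 at 1.79 ± 0.68, whereas Chrna5 was at 0.01 ± 0.37, Gucy1a1 at -0.13 ± 0.22 and Grp at -0.06 ± 0.38. Group means alone gave -1.39, 1.35 and 1.44 for Chrna5, Gucy1a1 and Grp (adjusted p = 0.0326, 0.0406 and 0.0342), so their values depend on the terms in the model.

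Over all 2784 genes changed in the knockout other than Satb2, 1971 (70.8%) had the opposite sign with SATB2. These genes were selected on libraries that both comparisons use; over all genes the share was 55.3%, against 46.1% in simulated unchanged groups. The correlation of both fold changes across genes, which are not independent replicates, was -0.169, against 0.124 in simulated unchanged groups, and the covariance was -0.0528 against 0.0158. The simulated noise was drawn for each gene alone, without swings that genes share. The gap to the simulated values is therefore not by itself evidence of reversal. The recovery slope was 0.301, with an error of 0.193 either way from the residual directions, where 0 is no reversal. It was 0.223 without SATB2 replicate 1, 0.388 without knockout GFP replicate 4 and 0.495 without knockout GFP replicate 3. Without floxed GFP replicate 4 it was 0.456, and in group means alone 0.679. There, simulations that kept the knockout change and reversed 0% of it already gave 0.614. With the knockout GFP libraries split 2 and 2 in 6 ways, the slope lay between 0.294 and 0.420 after subtraction of its error part, while the correlation across genes, with no such subtraction, ran from -0.232 to 0.322 and was above 0 in 4 of 6. In these splits, the median recovery of genes called in the first part lay between 0.0351 and 0.276. In group means alone the picture was far stronger, with 1637 reversed genes and a correlation of -0.948, but simulated unchanged groups with the same directions taken out gave -0.863 there. Simulations that kept the knockout change with 0% reversed gave -0.936 and 438 reversed genes.

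**Figure D3:**
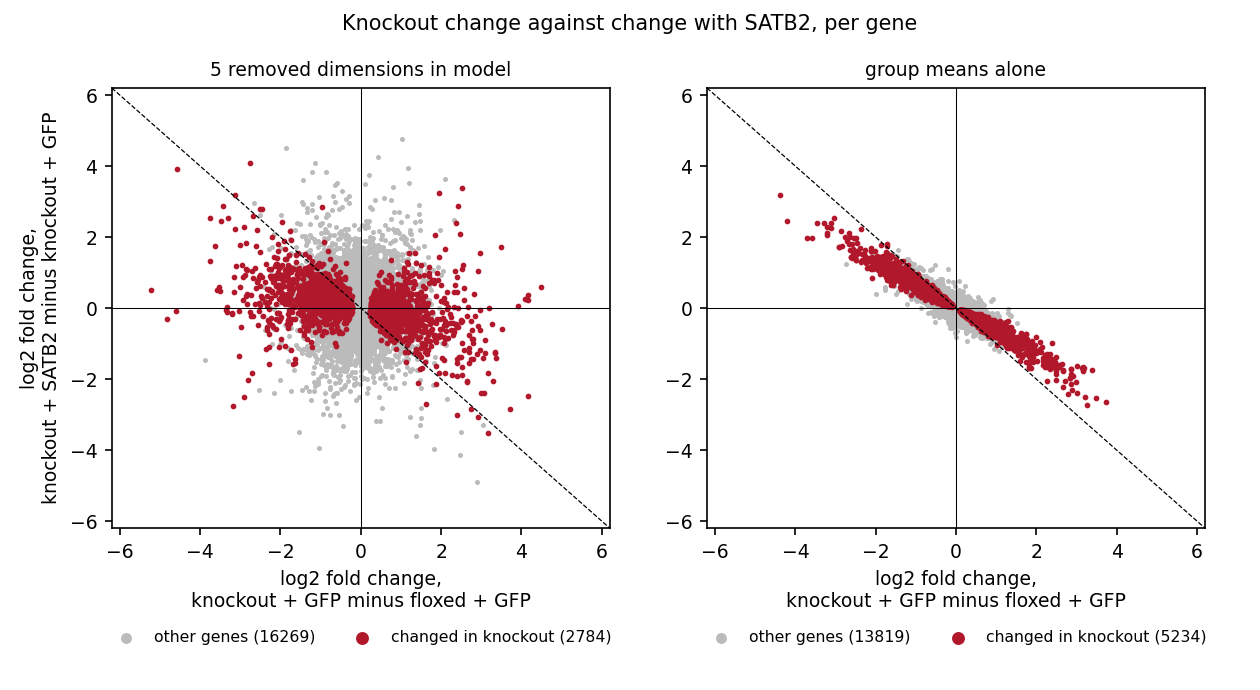
Log2 fold change per gene (19053 genes, Satb2 left out) of knockout SATB2 minus knockout GFP against knockout GFP minus floxed GFP, with genes changed in the knockout in red and full reversal as a dashed line. With the 5 taken-out directions in the model (left) the correlation is -0.169, and in group means alone (right) it is -0.948, where simulated unchanged groups give -0.863 and simulations of the knockout change with 0% reversed give -0.936.

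By list, 5 of 21 passed in the second comparison, all higher with SATB2, with 0 members past the threshold of limma over all genes. At an unadjusted p of 0.05, 10 of 29 rapid activity, 7 of 20 slower activity, 7 of 18 astrocyte, 2 of 11 oligodendrocyte lineage and 4 of 19 stress genes were higher, and 1 slower activity gene was lower. Rapid activity genes had a median of 0.41 (adjusted p = 9.05e-11, and adjusted p = 0.459 with an estimated correlation), with Npas4 at 0.87 ± 0.19 and Egr1 at 0.20 ± 0.16, and 5 of 29 members passed when adjusted over the list alone. Astrocyte genes had a median of 0.68 (adjusted p = 1.74e-07, and adjusted p = 0.459 with an estimated correlation), although 0 of 18 passed over the list alone and Slc1a2 was at 0.06 ± 0.16. In group means alone the astrocyte call ended, with a median of 0.21 (adjusted p = 0.471), and the rapid activity list, also at 0.21, passed (adjusted p = 2.19e-05). Slower activity genes were at 0.27 (adjusted p = 0.000696, and adjusted p = 0.459 with an estimated correlation; 5 higher and 1 lower over the list alone). The oligodendrocyte lineage list stood at 0.40 (adjusted p = 0.0136, and adjusted p = 0.459 with an estimated correlation; 2 of 11 over the list alone), and the cell stress list at 0.12 (adjusted p = 0.00869, and adjusted p = 0.560 with an estimated correlation; 3 of 19 over the list alone). Upper-layer genes had a median of 0.11 and subcerebral genes of -0.04, without passing (adjusted p = 0.0793 for both). In group means alone, which mix the groups, both lists passed camera. The upper-layer list was there at 0.43 (adjusted p = 0.000538, 13 higher and 3 lower). The subcerebral list was at -0.20 (adjusted p = 0.0188, 1 higher and 7 lower). The count of 7 was 1637 in group means alone, 6 of them shared, and 19 without a low-value filter. With only the 2 groups in the fit, which left 1 residual degree of freedom, it was 83. The count became 1 without knockout GFP replicate 2 or floxed GFP replicate 3. It was 2 without SATB2 replicate 1 or 3 or floxed GFP replicate 4, 14 without knockout GFP replicate 4, 17 without floxed GFP replicate 1 or 2, and 36 without SATB2 replicate 4. Of 60 values of the 5 named genes with a library left out, 31 lost the call. The count of 5 lists was 8 in group means alone and became 8 without floxed GFP replicate 1 or knockout GFP replicate 1, 9 without floxed GFP replicate 3, 10 without floxed GFP replicate 4 or knockout GFP replicate 4, and 12 without SATB2 replicate 4. The rapid activity and stress lists turned to lower without floxed GFP replicate 4, with adjusted p-values of 0.665 and 0.205. The stress call was also lost without floxed GFP replicate 3 (adjusted p = 0.585) and knockout GFP replicates 3 and 4 (0.0614 and 0.0924). The slower activity call was lost without floxed GFP replicate 4 (0.397) and knockout GFP replicates 3 and 4 (0.0827 and 0.230). Loss of the oligodendrocyte call followed from leaving out knockout GFP replicate 2 (0.0659) or SATB2 replicate 1 (0.160).

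The third comparison asks how far knockout cultures with SATB2 still differ from floxed cultures. Of 19 subcerebral genes 5 were higher, of 14 layer 6 genes 3 were higher, and of 25 upper-layer genes 2 were lower. As lists these passed camera with its preset correlation, but not the weaker test with an estimated one (subcerebral adjusted p = 0.464, layer 6 and upper-layer 0.523). Bcl11b was higher by 1.64 ± 0.17 (SE, n = 4 per group; adjusted p = 0.00138), Sox5, a layer 6 transcription factor gene, by 1.30 ± 0.17 and Crym by 2.37 ± 0.32 (adjusted p = 0.00984). In group means alone they were at 0.72, 0.48 and 0.91, and the calls of all 19 genes named by the rule in this comparison ended. Prdm8, a transcriptional regulator (chromosome 5, 98167198 to 98188991, plus strand), stood at -1.39 ± 0.18 (adjusted p = 0.00438) and Trpc6 (chromosome 9, 8544142 to 8680741, plus strand) at -2.44 ± 0.50 (adjusted p = 0.0456). In all, 158 genes passed, 88 higher and 70 lower, 136 of them by more than 2-fold, and after median-of-ratios rescaling 147 were higher and 72 lower.

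Of the 20 genes that the rule took for the knockout, 11 also passed here, among them Bmpr1b (2.43 ± 0.28), Chrna5 (3.21 ± 0.46), Ntng1 (1.92 ± 0.25), Gucy1a1 (-3.34 ± 0.28), Grp (-3.41 ± 0.47) and Tshz2 (-3.37 ± 0.42). Without Satb2, 156 of the 157 genes called here were also called in the knockout in the same direction (86 higher, 70 lower), where independent lists would share 6.10 and 5.32. The remaining gene was Adamts8, higher by 1.30 ± 0.20. Both comparisons use the floxed libraries: fold changes correlated at 0.665 across genes against 0.600 in simulated unchanged groups, and the covariance was 0.274 against 0.0946. Swings that genes share were absent from this simulated noise too. With the floxed libraries split 2 and 2 in 6 ways, between 10 and 168 genes were shared, the correlation lay between -0.0149 and 0.618, and the covariance between -0.0104 and 0.418.

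Of the 21 lists, 5 passed, against 8 in group means alone, 8 without knockout GFP replicate 3 and 14 without floxed GFP replicate 4. Upper-layer genes had a median of -0.57 with 2 of 25 lower, Rasgrf2 (-1.51 ± 0.21) and Dkk3 (-3.06 ± 0.52) (adjusted p = 9.55e-05, and adjusted p = 0.523 with an estimated correlation; 2 higher and 9 lower over the list alone). Of 19 subcerebral genes, 5 were higher, including Bcl6 (1.46 ± 0.22) and Npr3 (1.21 ± 0.18), with a median of 0.05 (adjusted p = 0.00314, and adjusted p = 0.464 with an estimated correlation; 7 and 2 over the list alone). Of 14 layer 6 genes, 3 were higher, with Sla at 1.35 ± 0.20 and Ppp1r1b at 1.36 ± 0.25, and a median of 0.34 (adjusted p = 0.000513, and adjusted p = 0.523 with an estimated correlation; 4 over the list alone). Astrocyte genes had a median of 0.74 with 1 of 18 higher, Gfap (1.43 ± 0.28) (adjusted p = 1.54e-08, and adjusted p = 0.523 with an estimated correlation; 3 over the list alone). Chromatin architecture genes had a median of -0.17 with 0 of 23 past the threshold of limma and 3 lower at an unadjusted p of 0.05; Chd4 was at -0.45 ± 0.18 and Ski at -0.17 ± 0.16 (adjusted p of the list = 0.0122, and adjusted p = 0.942 with an estimated correlation; 0 over the list alone). Rapid activity genes were at 0.11 and slower ones at -0.20, without passing (adjusted p = 0.200 and 0.305). In group means alone the 5 lists passed with smaller medians except for the subcerebral list: -0.25 for upper-layer, 0.07 for subcerebral, 0.11 for layer 6, 0.13 for astrocyte and -0.04 for chromatin genes. The chromatin call was lost without knockout GFP replicate 3 (adjusted p = 0.245), SATB2 replicate 1 (0.140), and floxed GFP replicates 2 and 4 (0.0546 and 0.619). Group means alone gave 0 calls in limma (1177 at an unadjusted p of 0.05, where chance gives 953), and the count of 158 fell to 2, 4 and 8 without floxed GFP replicate 3, floxed GFP replicate 4 and knockout GFP replicate 3. It rose to 288 without floxed GFP replicate 1, and was 15 with the 2 groups alone in the fit, which left 1 residual degree of freedom.

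**Figure D4:**
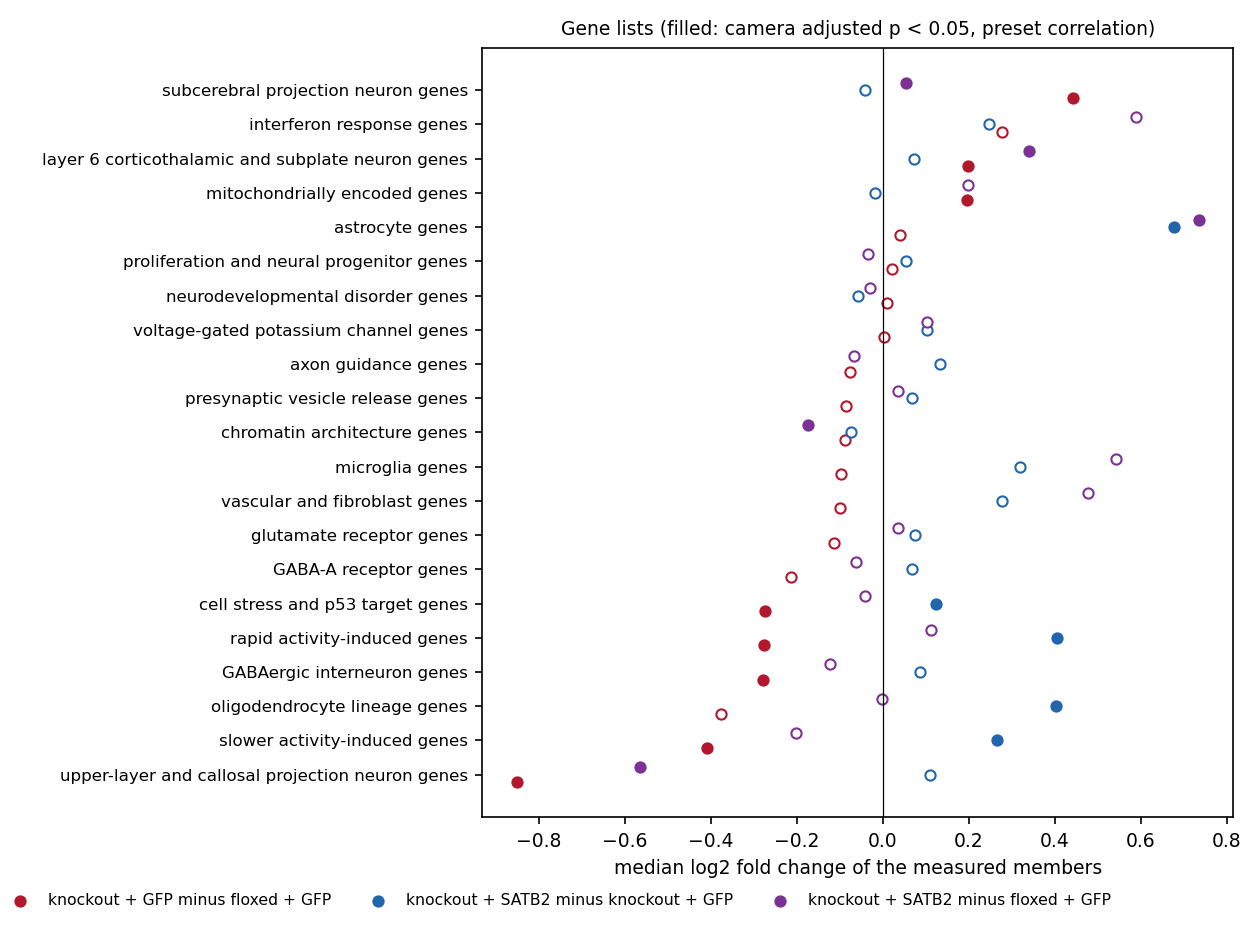
Median log2 fold change of the measured members of each of the 21 gene lists in the 3 comparisons; filled points passed camera with the preset correlation. Upper-layer and callosal genes are at -0.85 in the knockout, at 0.11 for SATB2 against knockout and at -0.57 for SATB2 against floxed cultures.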

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

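In groups of 4 libraries, a library was set apart where its gap to the nearest other library took up nearly the whole range of the group (Dixon's ratio). Of 153 groups tested, 9 (5.88%) stood apart in this way, where chance gives about 1 in 20. The directions taken out of the values also tie the libraries of a group together, which the ratio does not allow for. No explanation was tested for these values.

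Knockout GFP replicate 3 had 288 genes at 0 against 617 to 638 in the other 3 libraries of its group (ratio 0.940). It is also the library without which the count of genes changed in the knockout was lowest, at 750. Knockout SATB2 replicate 1 was low in Cr2, with a log2 value of 7.73 against 8.37 to 8.42 (ratio 0.931), and in Ntng1, with 8.72 against 9.08 to 9.15 (ratio 0.835). Knockout GFP replicate 2 was high in Grp, with 6.88 against 6.17 to 6.21 (ratio 0.945). Knockout SATB2 replicate 3 was low in Adamts1, with 10.76 against 11.36 to 11.40 (ratio 0.934). Knockout GFP replicate 1 was low in Prdm8, with 10.75 where the highest of the other 3 was 11.05 (ratio 0.839). Mean log2 values of lists set apart knockout GFP replicate 2 for oligodendrocyte lineage genes (6.65, where the highest other library was at 7.06, ratio 0.841) and for voltage-gated potassium channel genes (10.82 against 11.04 to 11.08, ratio 0.836). Knockout SATB2 replicate 1 was high for microglia genes (6.91 against 6.66 to 6.69, ratio 0.860).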

How the results depend on the processing

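The limma model with 5 terms, which gives the main results, was chosen after seeing the data. So were the limma fit of group means alone and the pseudocounts. The plan named a count test with group means and without covariates. The count-based tests and scalings (DESeq2, voom, and TMM against RLE in edgeR) were not run because the values are not counts. Depth is unknown, so its limit on low genes cannot be stated. Median-of-ratios rescaling and both pseudocounts left every total of changed genes within 1.5 times and every Satb2 call in place. The rescaling gave 1535 higher and 1333 lower, 8 and 2, and 147 and 72, against 1336 and 1449, 5 and 2, and 88 and 70. The causes of the changes below were not tested; fits with fewer libraries also have fewer residual degrees of freedom. The 3 counts of changed genes are given as knockout against floxed, SATB2 against knockout, and SATB2 against floxed. Group means alone gave 5235, 1637 and 0 genes, 1637 reversed, a recovery slope of 0.679 (0.614 in simulations with 0% reversed), a Satb2 difference of 0.16 for SATB2 against floxed (adjusted p = 0.988), and 8 lists in each SATB2 comparison. Without a low-value filter 19 genes passed in SATB2 against knockout and 15 were reversed. With only the 2 groups of a contrast, 83 passed in SATB2 against knockout and 15 in SATB2 against floxed. Those fits left 1 residual degree of freedom. With an estimated correlation, 0 lists passed in the knockout comparison, 0 in SATB2 against knockout and 0 in SATB2 against floxed.

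Replicate numbers did not pair the samples: 2 of 12 same-number pairs correlated above 0.1 (range -0.669 to 0.609), and 2 of 12 libraries correlated best with their own number. The replicate block, which left 1 residual degree of freedom, gave 1293, 32 and 158 genes, 10 reversed, a slope of 0.208, and 4 lists in the knockout comparison. Of these genes, 1088, 4 and 67 were shared with the main fit, so the equal total of 158 holds largely other genes. The block ended the calls of 24 of 83, 3 of 5 and 9 of 19 named genes in the same order.

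Leaving out each library gave 750 to 2959 genes for the knockout, 1 to 36 for SATB2 against knockout and 2 to 288 for SATB2 against floxed, 0 to 22 reversed, and a slope of 0.223 to 0.495. The 7 genes of SATB2 against knockout became 1 without knockout GFP replicate 2 or floxed GFP replicate 3, 2 without SATB2 replicate 1 or 3 or floxed GFP replicate 4, 14 without knockout GFP replicate 4, 17 without floxed GFP replicate 1 or 2, and 36 without SATB2 replicate 4. Satb2 differences were -1.80 to -1.27, 5.89 to 7.33 and 4.27 to 5.70. Lists passing were 7 to 9, 4 to 12 and 4 to 14. In SATB2 against knockout, the rapid activity list ranged in adjusted p from 5.46e-31 to 0.665 and the stress list from 1.37e-05 to 0.585, both turning to lower without floxed GFP replicate 4 (0.665 and 0.205). Of 83 named knockout genes, 906 of 996 values kept their call, as did 29 of 60 for the 5 genes of SATB2 against knockout and 136 of 228 for the 19 of SATB2 against floxed, and none changed sign in these fits. Group means alone ended the calls of 2, 0 and 19 of these genes, and fits of 2 groups those of 5, 3 and 18.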

Other observations

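Chosen only after the results were seen were the test of the recovery slope and the simulations with reversal, both rotation tests, the comparison of presynaptic with activity genes and the count of interneuron genes that rose.

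Genes that guide axons changed in both directions in the knockout, with 9 of 36 higher, 11 lower and 16 not past the threshold, so that the list did not pass (median -0.08, adjusted p = 0.951; 10 higher and 13 lower over the list alone). The ephrin receptor gene Epha4 changed by -2.47 ± 0.12 and the semaphorin gene Sema6a by -1.13 ± 0.09, while the semaphorin receptor gene Nrp2 rose by 2.22 ± 0.11 and the repellent gene Slit2 by 1.05 ± 0.08. In knockout cultures with SATB2 against floxed cultures, Epha4 stood at -1.60 ± 0.24, Nrp2 at 1.80 ± 0.23 and Slit2 at 1.20 ± 0.16, all past the threshold. Of 24 glutamate receptor genes, 3 were higher and 7 lower (adjusted p = 0.363; 4 and 8 over the list alone). Grm3 changed by -1.81 ± 0.28 and Grm2 by -0.93 ± 0.09, and the kainate receptor gene Grik2 rose by 0.74 ± 0.08. Of 13 GABA-A receptor genes, 3 fell (Gabra4 -0.71 ± 0.11, Gphn -0.35 ± 0.07, Gabra5 -0.35 ± 0.08; adjusted p of the list 0.167; 4 lower over the list alone). Of 24 voltage-gated potassium channel genes, 2 rose (Kcna6 0.62 ± 0.09, Kcna4 0.55 ± 0.11) and 3 fell, with Kcnab1 at -1.18 ± 0.11 and Kcnh1 at -0.67 ± 0.12 (adjusted p = 0.954; 3 and 6 over the list alone). Of 19 presynaptic release genes, 2 fell (Rims2 -0.33 ± 0.09, Stxbp1 -0.25 ± 0.07; adjusted p = 0.743; 0 higher and 1 lower over the list alone).

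The lists of other cell types and processes in this paragraph did not pass in the knockout. Of 11 oligodendrocyte lineage genes, with a median of -0.38, 1 fell, Lhfpl3 (-1.75 ± 0.12; adjusted p of the list 0.167; 1 over the list alone). Of 5 microglia genes, 1 fell, Cd68 (-0.89 ± 0.21; adjusted p 0.954; 1 and 1 over the list alone). Of 12 vascular and fibroblast genes, Col1a2 rose by 1.42 ± 0.23 and 2 fell, Acta2 (-2.11 ± 0.43) and Tagln (-0.98 ± 0.27; adjusted p 0.954; 1 and 2 over the list alone). Of 11 proliferation and progenitor genes, 1 fell, Sox2 (-0.56 ± 0.14; adjusted p 0.951; 1 over the list alone). Of 10 interferon genes, with a median of 0.28, 1 rose, Stat1 (0.56 ± 0.13; adjusted p 0.287; 2 over the list alone). Of 35 neurodevelopmental disorder genes, 3 rose and 3 fell, with Bcl11b at 2.31 ± 0.08, Mef2c at -0.82 ± 0.16 and Foxp1 at -0.40 ± 0.10 (adjusted p 0.541; 3 and 3 over the list alone). Of 23 chromatin architecture genes, 3 fell, the remodeller gene Chd4 (-0.39 ± 0.09), Stag1 (-0.30 ± 0.09), a cohesin subunit, and Lmna (-0.27 ± 0.07), which encodes lamin A (adjusted p 0.0667; 3 over the list alone). Median, mean and test differed in sign for microglia (-0.10, 0.15, higher), proliferation (0.02, 0.03, lower) and potassium channel genes (0.00, -0.14, lower) in the knockout, and for proliferation genes with SATB2 against knockout (0.05, -0.02, higher). For SATB2 against floxed they differed for interneuron (-0.12, 0.06, lower), oligodendrocyte (-0.00, 0.20, higher), proliferation (-0.03, 0.01, higher), glutamate receptor (0.03, -0.03, higher), potassium channel (0.10, -0.00, higher) and axon guidance genes (-0.07, -0.00, higher), none of which passed as lists.

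For each of the 3 counts of changed genes, the real grouping gave more genes than any other split of its libraries. In the knockout comparison 1 of 35 splits of the 8 libraries, the real one, gave as many as 2785 genes, and the highest other split gave 1539. For SATB2 against knockout it was 1 of 35, with 7 genes against 1, and for SATB2 against floxed 1 of 35, with 158 against 8. A result of 1 of 35 is the lowest this test can give, and it was not adjusted for the 3 comparisons. The taken-out directions were not balanced over the groups, so the splits may differ in error and need not be comparable. Chance is therefore not excluded by these counts. The 7 genes include Satb2 itself, and that count ran from 1 to 36 with single libraries left out.

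In group means alone, 1637 genes changed in opposite directions in the knockout and with SATB2, against 6 with the taken-out directions in the model. Simulated libraries in which SATB2 reversed nothing, with the same 5 directions taken out, gave a median of 438 opposite calls in group means and 0 in the fuller model. That is neither close to the observed 1637 nor a negligible part of it, so how much of the pattern comes from mixed group means cannot be told apart from a real reversal by this count. In all these simulations only the 2785 genes called in the knockout by the fuller model carried a change, where group means alone called 5235. The simulated counts therefore need not match the data. Reversal of part of the knockout change remains a candidate explanation, since the recovery slope of 0.301 lay above the 0.193 that the residual directions allow. Simulated libraries with 30% reversal gave 1777 opposite calls in group means. That share lies at the observed slope and was set after the results were seen, so the count near 1637 is no separate support. In the fuller model these libraries gave medians of 29 opposite calls, 32 genes in SATB2 against knockout and 365.5 in SATB2 against floxed. The observed counts there were lower, at 6, 7 and 158. Full reversal in the simulation gave a slope of 1.01 and 1317 reversed genes in the fuller model, far from the values seen.

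Of the activity-induced genes, 6 of 29 rapid and 11 of 20 slower ones fell in the knockout and 2 slower ones rose, with a median of -0.34 over 49 genes. Swings of co-varying genes from library to library as the whole cause are argued against by a two-sided p of 0.0421 for the median when the contrast was rotated among the residual directions. That value lies close to the threshold, and camera with an estimated correlation did not pass for the rapid and slower lists (adjusted p = 0.778 and 0.610). A lower share of neurons stays open: presynaptic genes, among them Slc17a6 and Slc17a7 of excitatory neurons, had a median of -0.09, above the activity median by 0.253, which is less than 2 times its error of 0.133. A weaker response of knockout neurons to bicuculline may also contribute, and was not tested because no unstimulated libraries were analysed here.

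Of 24 interneuron genes, 7 fell, 2 rose and 15 did not pass in the knockout, with a median of -0.28 (adjusted p = 0.778 with an estimated correlation). A loss of all interneuron types alike would lower all of their markers. In limma 2 of the 24 genes rose, Vip (0.82 ± 0.11, adjusted p = 0.000251) and Htr3a (0.45, adjusted p = 0.0224), which such a loss alone would not give. As many random genes would give 1.68 risers (p = 0.509 in a one-sided Fisher's exact test across genes, which are not independent). That comparison asks only whether risers are more frequent than among random genes, so it does not decide on a loss. A loss of interneurons beside other changes stays open. A loss of the Sst and Npy types alone was not tested. Library swings cannot be told apart from a group difference, since the two-sided rotation p was 0.0932 with 4 residual degrees of freedom.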
